A study of Macaca fascicularis with 86 samples.

How the data were processed

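The series holds RNA sequencing of 86 laser-captured regions from cryosections of 3 crab-eating macaque embryos, 2 at E18 and 1 at E20. The deposited table gives TPM per gene, as computed by the authors, with 17023 genes and 1 column per region. The labels name fastp, HISAT2 and StringTie without versions, and the genome build and annotation are not given in the sources used here, so no coordinates are stated. Columns sum to between 495547 and 777987.5 TPM, so some of the genes that were normalized over are not in the table. POU5F1, LEFTY2 and HBE1 were among the genes looked for and are not analysed here. The columns were matched to the labels by stage, embryo, section and sector, with 0 columns unmatched. TPM keeps no counts, so the depth per region is unknown and no counting interval or detection floor is given. As a check on capture, ACTB and GAPDH were listed at 0 in 0 of 86 regions and HPRT1 in 6.

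Genes at a TPM of at least 1 in at least 10 regions were tested (15216 genes), as log2(TPM + 1). Models were fitted with limma 3.58.1 (eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The embryo was the replicate in the stage comparison and in the alternative that tested embryo slopes. The section, sector and score models were fitted to single regions. Their SE and p-values treat regions of an embryo as independent beyond the blocks named below. For the stage comparison the regions of each embryo were averaged and the E20 embryo was set against the 2 E18 embryos, with 1 residual degree of freedom moderated over genes (infinite prior degrees of freedom). The difference between the E18 embryos was computed without a test. For the section trend, log2 values were regressed on section number scaled from 0 at the first to 1 at the last section of its embryo, with embryo as a block. For the sector trend, they were regressed on sector number scaled in the same way within its section, with section within embryo as a block. Slopes were also fitted per embryo and compared between embryos by a moderated F test. For 7 marker lists, a score was made per region as the mean of the list's z-scored log2 values within an embryo, and each gene was regressed on it with embryo as a block. A list member was tested against the score made without it.

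Before the data were examined, 29 gene lists were fixed: pluripotent epiblast, primitive streak and nascent mesoderm, later mesoderm, definitive endoderm and node, hypoblast and yolk sac endoderm, amnion and surface ectoderm, extraembryonic mesenchyme, neural ectoderm, blood and endothelium, primordial germ cell, trophoblast, immune and decidual cells, posterior and axial progenitor, HOX, BMP, WNT, NODAL and FGF pathways, retinoic acid, epithelial, mesenchymal transition, basement membrane, S phase, G2 and M phase, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein, mitochondrially encoded, and immediate early and heat shock. The comparisons, most alternatives and the rule for named genes were fixed at the same time. Lists were tested with limma's cameraPR at a preset correlation of 0.01 and again with the correlation estimated from region residuals (statmod 1.5.0 was loaded for correlation estimates). The test compares a list with all genes tested. At the preset correlation 15 lists passed for the stage, 13 for the section trend and 16 for the sector trend, and with an estimated correlation 2, 0 and 3.

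Named genes are those past the threshold with a mean TPM of at least 5: the 10 largest effects in each direction, for trends and scores only with the same sign in 3 of 3 embryos. Called members of the fixed lists, largest effects first, and a fixed panel of 26 developmental genes were also open to naming. Correlations between scores were computed with numpy 2.4.6 and scipy 1.17.1, with 100000 permutations (exact for 8 regions) and two-sided p-values. Pictures were drawn with matplotlib 3.10.9.

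Alternatives were a pseudocount of 0.1, no filter, a stricter filter (TPM of at least 5 in at least 20 regions), quantile normalization, other summaries over regions, an estimated correlation within embryos (limma's duplicateCorrelation), section means, sector numbers as given, the number of genes detected as a covariate, embryo slopes tested against 0, and leaving out each embryo. Added after seeing the data were a version without the mitochondrially encoded genes, rescaled to a common sum, each E20 section alone, E20 sections 1 to 5 and 6 to 7 as separate blocks, and alternatives for the comparison of slopes and for the E18 difference. Other splits were counted by taking each embryo in turn as the lone one, and by 100 orders of sections or sectors or shuffles of scores within embryos.

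The models were tested on simulated data with 200 planted genes. A slope of 2 log2 units was recovered for 95.5% of genes along sections and along sectors, a slope of 1 per SD of a score for 99.0%, and a stage difference of 2 for 68.5%. At effects of 4 (2 for scores) 100.0% were recovered. Between 2.44% and 7.41% of calls were false. For correlations with a planted r of 0.7, 199 of 200 pairs were recovered and 10 of 200 independent pairs passed. A planted change of the HOX list was called with 0 of 28 other lists. The simulated noise was independent between genes and regions, while real regions share sections and embryos and list genes vary together. These rates therefore hold for independent values and do not give the share of false calls in the real data.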

Results

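Polyadenylated RNA was sequenced from 86 laser-captured regions of sectioned, gastrulating embryos of the crab-eating macaque, with 5 to 50 cells per region (Geo-seq, a method for spatial transcriptomes of small tissue samples). E18 embryo 1 gave 15 regions from 4 sections, E18 embryo 2 gave 35 regions from 6 sections and the E20 embryo gave 36 regions from 7 sections. The labels number the sections of an embryo and the sectors of a section. They name no germ layer and do not say at which end the numbering starts. The deposited values are TPM, a length-scaled share of the reads, for 17023 genes. They keep no read counts, so the depth behind each value is unknown. Genes at a TPM of at least 1 numbered 10343 ± 855 per region in E18 embryo 1 (SD, n = 15 regions), 12415 ± 779 in E18 embryo 2 (n = 35) and 9045 ± 1195 in the E20 embryo (n = 36). Mitochondrially encoded genes held 16.9% ± 7.60 (SD) of the summed TPM in E18 embryo 1, 31.5% ± 11.6 in E18 embryo 2 and 17.9% ± 4.10 in the E20 embryo.

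For the median gene, 19.01% of the sum of squares lay between the 3 embryos, 14.5% between sections of an embryo and 65.05% between sectors of a section. The shares grow with the number of embryos, sections and sectors compared, and the last also holds the noise, so they do not rank the 3 levels. Section labels shuffled within embryos gave a median section share of 12.4% and at most 15.2% over 100 draws. Between the E18 embryos, 1662 genes had a mean at least 1 log2 unit higher in embryo 2 and 207 a mean at least 1 lower, with a median over all genes of 0.41. After quantile normalization the median was 0.022 and 998 genes in all were at least 1 apart, and with a pseudocount of 0.1 they were 6073. This comparison sets 1 embryo against 1 and has no test.

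The comparison of stages asked which genes differed between E20 and E18. Genes for plasma proteins, which yolk sac endoderm makes before the liver does, stood highest at E20 relative to E18. The fibrinogen chain FGB was higher by 8.46 ± 0.46 on the log2 scale (SE), alpha-fetoprotein (AFP) by 8.40 ± 0.50 and FGG by 8.18 ± 0.53. The SE and the calls of this comparison rest on the difference between the 2 E18 embryos (1 residual degree of freedom), pooled over genes with infinite prior degrees of freedom. They hold nothing on variation among E20 embryos, and E18 embryo 2 taken as the lone embryo also gave 1303 genes. Apolipoprotein A1 (APOA1) averaged 7601 ± 7333 TPM in the E20 regions (SD, n = 36), 795 ± 1425 in E18 embryo 1 (n = 15) and 51.7 ± 60.4 in E18 embryo 2 (n = 35). Genes of pluripotent cells were lower at E20: L1TD1, an RNA-binding protein of such cells, by -4.73 ± 0.43, DPPA5 by -4.22 ± 0.49 and SOX2 by -3.75 ± 0.53. SOX2 averaged 8.78 ± 22.1 TPM at E20 against 49.5 ± 45.8 and 61.2 ± 69.6 in the E18 embryos.

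The differences of the yolk sac, epiblast and primitive streak lists were not shared by the whole E20 embryo. Setting each E20 section alone against the E18 embryos, an alternative chosen after seeing the data, separated sections 1 to 5 from sections 6 and 7. The hypoblast and yolk sac endoderm list had a median difference of 7.34 in section 1, 5.41 in section 2, 8.07 in section 3, 7.92 in section 4 and 8.09 in section 5. In sections 6 and 7 the list's median difference was -0.93 and -0.98. The epiblast list had medians from -3.23 to -2.71 in sections 1 to 5, -0.21 in section 6 and -0.16 in section 7. For the primitive streak list they were -2.40 to -2.18 in sections 1 to 5, -0.47 in section 6 and -0.34 in section 7. These are differences in level, with 1 section on the E20 side and only the E18 pair to give a spread. Such medians were computed only for these lists, and other list differences given below may follow the same split. As mean log2(TPM + 1), amnion list levels were 1.33 to 2.57 in regions of sections 1 to 5. They were 1.39 to 6.33 in sections 6 and 7, and 1.57 to 5.42 and 1.78 to 6.36 in the E18 embryos. Mesenchyme list levels were 3.30 to 7.20 in sections 1 to 5 and 1.53 to 7.62 in sections 6 and 7. In the E18 embryos they were 1.65 to 7.79 and 1.94 to 8.44. Some differences were shared: H2BC21 stood at -3.16 in section 6 and -3.10 in section 7, H2AC14 at -1.89 and -1.96, MYO19 at -1.81 and -1.998 and H1-5 at -1.78 and -1.97. These 4 genes, called in both sections, were chosen after their values were seen. Both sections were set against the same 2 E18 embryos, so the agreement between them is partly built in.

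**Figure D1:**
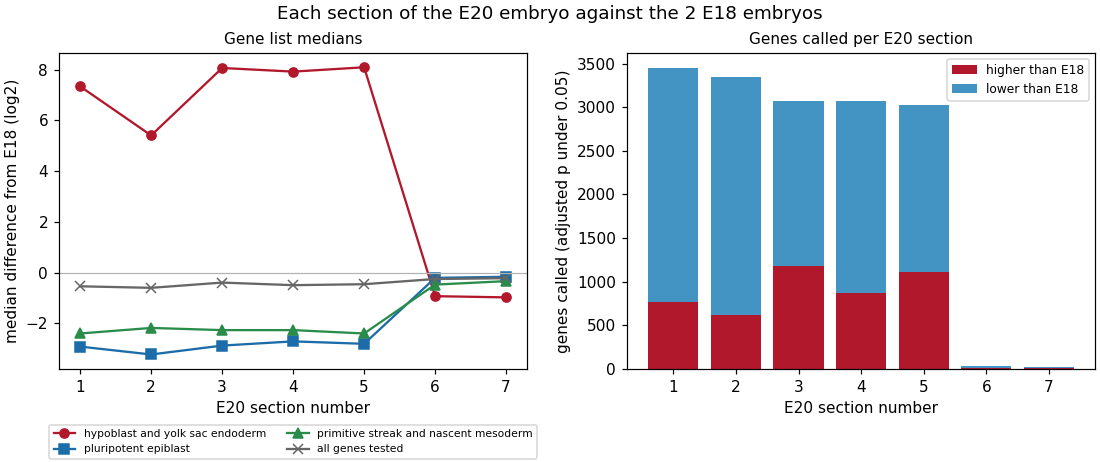
Each E20 section set against the 2 E18 embryos. Left, the median log2 difference of 3 gene lists and of all genes tested by E20 section number; right, the number of genes called higher or lower (limma, adjusted p under 0.05), for which the E18 pair alone gives the spread. The yolk sac list lies at 5.41 or above in sections 1 to 5 and at -0.93 and -0.98 in sections 6 and 7.

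Over all regions, 1734 of 15216 genes differed between stages (limma on embryo means), 402 higher and 1332 lower at E20, against a median of -0.44 over all genes. After quantile normalization 796 were higher and 679 lower. Besides FGB, AFP and FGG, the 10 largest increases were those of fetuin-A (AHSG) at 7.29 ± 0.59, retinol-binding protein (RBP4) at 7.17 ± 0.50 and transferrin (TF) at 7.10 ± 0.62. They were followed by APOA2 at 7.00 ± 0.52, FGA at 6.87 ± 0.61, SERPINA1 at 6.50 ± 0.58 and the water channel AQP1 at 5.75 ± 0.51. In the other direction, L1TD1 and DPPA5 were joined by the amino acid transporter SLC7A3 at -4.24 ± 0.46, OTX2 at -4.10 ± 0.48, TMEM54 at -4.10 ± 0.44 and the NODAL effector FOXH1 at -4.07 ± 0.44. The remaining genes were the histone H2AC14 at -4.06 ± 0.44, CNFN at -3.91 ± 0.43, ZIC2 at -3.85 ± 0.51 and CA11 at -3.80 ± 0.48. Each of these genes differed in the stated direction from both E18 embryos.

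By gene list, 14 of 19 hypoblast and yolk sac endoderm genes rose (15 rose and 1 fell adjusted over the list alone), with a list median of 5.34 and adjusted p = 9.57e-11 with an estimated correlation. In the pluripotent epiblast list 11 of 13 genes fell (11 adjusted over the list alone), among them TDGF1 at -3.28 and DNMT3B at -3.07, with a median of -2.29 and adjusted p = 0.0152 with an estimated correlation. The other calls made at the preset correlation were lost with an estimated one. Of 16 primitive streak and nascent mesoderm genes 6 fell (11 adjusted over the list alone), with EOMES at -3.51, FGF17 at -3.44, LHX1 at -3.21 and MIXL1 at -2.51 (adjusted p = 0.192 with an estimated correlation). In E20 sections 6 and 7 alone, the differences from E18 were above 0 for EOMES (0.53 and 0.71) and MIXL1 (1.62 and 1.49). With 1 section on the E20 side, these values do not show that either gene was higher at E20. Of 8 neural ectoderm genes OTX2, ZIC2 and HESX1 fell (4 adjusted over the list alone; adjusted p = 0.05115 with an estimated correlation). Of 15 extraembryonic mesenchyme genes 6 rose (7 adjusted over the list alone), with the matrix genes LUM at 5.26, COL3A1 at 3.76 and DCN at 3.16 (adjusted p = 0.0648 with an estimated correlation). Mesenchyme levels differed between E20 sections, as given above, so this rise may not be shared by the whole E20 embryo. In the blood and endothelium list of 14, embryonic globin HBZ rose by 4.40, TEK by 3.11 and KDR by 1.73, and EGFL7 fell by 1.63. The counts adjusted over the list alone were 4 and 1 (adjusted p = 0.117 with an estimated correlation).

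Among signalling lists, FGF pathway genes fell in 4 of 15 cases (8 adjusted over the list alone), with FGF17 first and ETV4 at -3.29, and adjusted p = 0.0648 with an estimated correlation. The NODAL pathway had the same p, with FOXH1, TDGF1 and CER1 lower and 1 gene higher among 7 (4 lower and 1 higher adjusted over the list alone). In the retinoic acid list of 8, CYP26A1 at -3.48 and CRABP2 at -1.97 fell and DHRS3 rose by 1.80 (4 and 1 adjusted over the list alone; adjusted p = 0.0648 with an estimated correlation). BMP pathway genes fell in 6 of 13 cases (9 adjusted over the list alone), with ID1 at -2.65, CHRD at -2.33 and BMP4 at -1.75 (adjusted p = 0.242 with an estimated correlation). The WNT pathway list of 16 had 3 genes lower, WNT5B at -2.37 first, and FRZB higher by 3.10 (9 and 1 adjusted over the list alone). It passed with neither correlation (adjusted p = 0.593 with an estimated correlation).

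Replication genes fell in 4 of 10 S phase cases (5 adjusted over the list alone), with MCM3 at -1.91, and in 3 of 12 G2 and M phase cases (4 adjusted over the list alone), with PLK1 at -1.90. Both lists had adjusted p = 0.574 with an estimated correlation. The basement membrane list had the same p, and there NID2 and LAMB1 rose among 8 genes by 2.84 and 1.61. That list had a median of -0.24, a mean of 0.15, a test pointing up and a median of 0.21 after quantile normalization (2 higher and 1 lower adjusted over the list alone). Oxidative phosphorylation had 1 of 47 genes higher and 1 lower (0 adjusted over the list alone) with a median of 0.65 (adjusted p = 0.379 with an estimated correlation). Of 54 ribosomal protein genes 0 were called (limma, 1 at an unadjusted p under 0.05). Their list median of 0.20 became -0.23 after quantile normalization and -0.057 without mitochondrially encoded genes (adjusted p = 0.673 with an estimated correlation).

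The other lists passed with neither correlation, with adjusted p from 0.0986 to 0.869 at the preset correlation. Of 12 definitive endoderm and node genes 4 fell, with CER1 at -2.66 and CXCR4 at -2.52 (4 lower and 1 higher adjusted over the list alone). Of 15 amnion and surface ectoderm genes 4 fell, VTCN1 at -2.85 first, and IGFBP3 rose by 2.23 (6 and 1 adjusted over the list alone). Later mesoderm had APLNR lower among 14 genes, the posterior and axial progenitor list had NKX1-2 and WNT5B lower among 8, and the epithelial list had CLDN7 and CDH1 lower among 9 (3 adjusted over the list alone). PRDM1 rose by 2.60 among 7 primordial germ cell genes (1 higher and 2 lower adjusted over the list alone), CGA by 2.58 among 9 trophoblast genes and IGFBP1 by 2.62 among 11 immune and decidual genes. The mesenchymal transition list of 11 had VIM higher by 2.00 and ITGA5 lower by -1.65 (1 and 3 adjusted over the list alone), and the immediate early and heat shock list of 8 had HSPH1 lower by -1.37. No gene was called among 31 HOX, 9 glycolysis and hypoxia and 12 mitochondrially encoded genes (limma, 1, 1 and 0 genes at an unadjusted p under 0.05), nor adjusted over the list alone. The list test compares with all genes, whose median was below 0. It pointed up for the later mesoderm, HOX, trophoblast, immune, mesenchymal transition, mitochondrially encoded and heat shock lists although their medians and means were below 0. For the germ cell list it pointed up with a median of -0.14 and a mean of 0.067, and for glycolysis with a median of 0.21 and a mean of -0.016. After quantile normalization the medians of the HOX (0.047), later mesoderm (0.23), heat shock (0.023), germ cell (0.26) and glycolysis (-0.23) lists had the other sign.

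With medians in place of means over regions, 0 genes passed for the stage (limma, 2021 at an unadjusted p under 0.05). Without the mitochondrially encoded genes 887 genes passed.

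Along the section numbers, the genes with the largest increases included genes of the primitive streak, node and definitive endoderm. As lists, neither group held its call with an estimated correlation, and 9 genes of any kind passed without the E20 embryo. FGF17, an FGF ligand, rose by 5.05 ± 0.74 on the log2 scale (SE, 86 regions; adjusted p = 6.71e-06), with slopes of 4.97, 6.10 and 4.04 in E18 embryo 1, E18 embryo 2 and the E20 embryo. The homeobox gene MIXL1 rose by 4.32 ± 0.66, with 3.97, 3.88 and 4.92, and CER1, a secreted antagonist of NODAL and BMP, by 4.24 ± 0.74, with 5.13, 4.49 and 3.58. FOXA2, a transcription factor of node and endoderm, rose by 3.02 ± 0.62, and TBXT, the T-box factor of the streak, by 2.47 ± 0.51 with slopes of 2.36, 3.25 and 1.73. TBXT reached a TPM of 1 in 6 of 15, 26 of 35 and 4 of 36 regions of these embryos, so its E20 slope rests on few regions. MIXL1 reached it in 12 of 36 E20 regions. The plasma protein gene SERPINA1 fell by 3.51 (SE 0.84), with slopes of -0.52 and -0.31 in the E18 embryos and -8.04 in the E20 embryo. The slopes of APOA1 were 3.19, 1.21 and -6.74 and those of TTR 1.23, 1.40 and -8.59, so both were below 0 in the E20 embryo only.

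**Figure D2:**
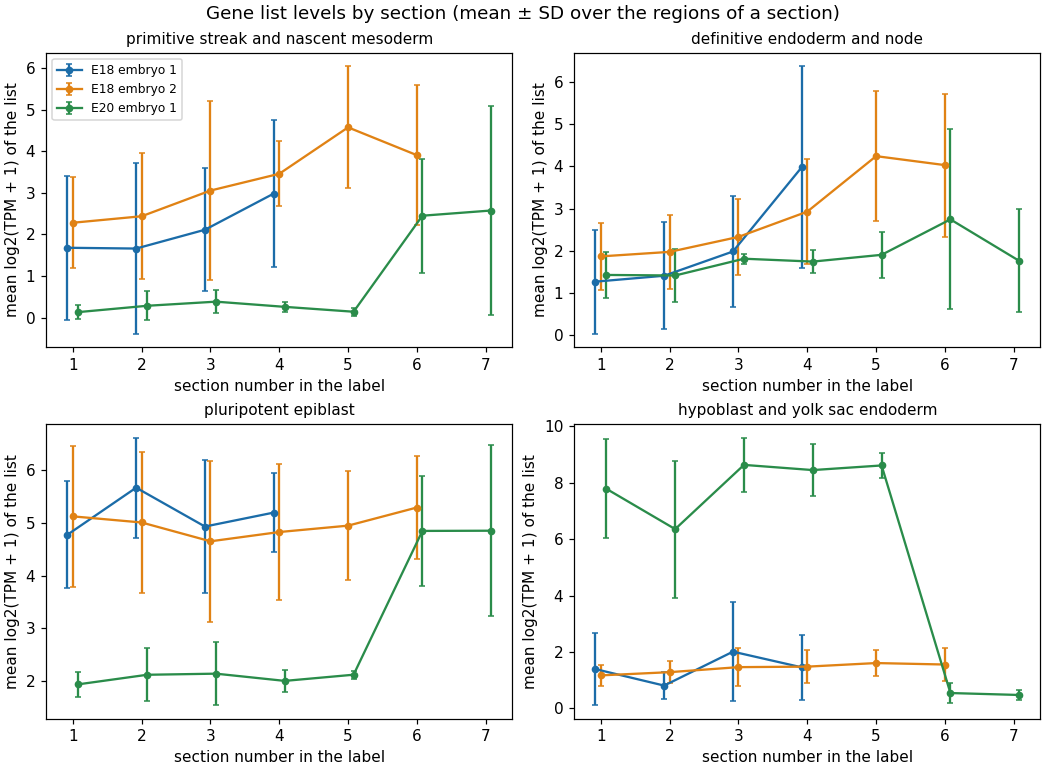
Mean level of 4 gene lists, as log2(TPM + 1), by section number; points are means and bars 1 SD over the regions of a section, with 1 line per embryo. Both the streak and the node list are highest in section 4 of E18 embryo 1, section 5 of E18 embryo 2 and section 6 or 7 of the E20 embryo. In the E20 embryo the epiblast and yolk sac lists step between sections 5 and 6.

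The model with embryo as a block called 1628 genes, 1341 rising and 287 falling (852 and 500 after quantile normalization), of which 1062 had the same sign in 3 of 3 embryos and 689 had slopes that differed between embryos. The calls pool the same embryos, so the count of equal signs is not an independent repeat. Over all genes tested, 27.3% had the same sign in 3 embryos, where chance gives 25% if both signs are equally frequent in each embryo. Other rising genes were the WNT antagonist DKK4 at 4.66 ± 0.78, LHX1 at 3.96 ± 0.70 and the BMP antagonist CHRD at 3.66 ± 0.63. OTX2 at 3.63 ± 0.66, EOMES at 3.38 ± 0.65 and the organiser gene GSC at 3.04 ± 0.46 followed. Falling genes with the same sign in 3 embryos were LUM at -3.31 ± 0.86, FABP1 at -2.62 ± 0.69, plasminogen (PLG) at -2.58 ± 0.68 and the hormone subunit CGA at -2.48 ± 0.66. The others were PARM1 at -2.47 ± 0.46, APOM at -2.40 ± 0.64, ARHGDIB at -2.35 ± 0.67, NID2 at -2.35 ± 0.63 and LGALS2 at -2.18 ± 0.53. In the E18 embryos PLG had slopes of -0.30 and -0.29, and APOM of -0.089 and -0.045. With E20 sections 1 to 5 and 6 to 7 as separate blocks the slopes of these genes changed sign. PLG, APOM and SERPINA1 had slopes of 0.33, 0.25 and 0.33, and none of them passed.

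Of 16 primitive streak and nascent mesoderm genes 9 rose (11 adjusted over the list alone), each with the same sign in 3 embryos, and adjusted p was 0.0803 with an estimated correlation. Of 12 definitive endoderm and node genes 8 rose (9 adjusted over the list alone), also with the same sign in 3 embryos, CXCR4 at 2.38 and SOX17 at 1.81 among them (adjusted p = 0.0803 with an estimated correlation). The NODAL pathway had 4 of 7 genes higher, with FOXH1 at 2.90 and NODAL at 2.09 (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0669 with an estimated correlation). FGF pathway genes rose in 7 of 15 cases (8 adjusted over the list alone), with DUSP6 at 2.26 and FGF4 at 2.21, and 4 of 8 neural ectoderm genes rose (5 adjusted over the list alone), with ZIC2 at 2.91. Both had adjusted p = 0.0803 with an estimated correlation. WNT pathway genes rose in 4 of 16 cases and FRZB fell by 1.72 (7 and 1 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). Epiblast genes rose in 8 of 13 cases (10 adjusted over the list alone), 6 of them with the same sign in 3 embryos, L1TD1 at 2.65 first (adjusted p = 0.324 with an estimated correlation).

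Hypoblast and yolk sac endoderm genes fell in 12 of 19 cases and 1 rose (14 and 1 adjusted over the list alone), with 2 of the called genes having the same sign in 3 embryos and adjusted p = 0.0871 with an estimated correlation. Ribosomal protein genes rose in 13 of 54 cases, RPL28 by 0.92 first, and RPL7 fell by 0.59 (15 and 1 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation). Of the 14 blood and endothelium genes KDR fell by 2.11, TEK by 1.81 and FLI1 by 1.72 (3 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation). Retinoic acid genes rose in 4 of 8 cases, with CYP26A1 at 2.98, and DHRS3 fell by 1.34 (4 and 1 adjusted over the list alone), a list that passed with neither correlation (adjusted p = 0.469 with an estimated correlation). No list held its call with an estimated correlation. The trophoblast, immune, mesenchymal transition, glycolysis and heat shock lists, none of which passed, had a median or mean of the opposite sign to their test.

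Within single embryos 3909 genes followed the sections in the E20 embryo and 0 in each E18 embryo (limma, 541 and 1027 at an unadjusted p under 0.05), and slopes differed between embryos for 1537 genes. Of the 3909 genes, 51.8% had a slope of the same sign in E18 embryo 1 and 55.6% in E18 embryo 2. Chance gives 50% only if E18 slopes lie as often above as below 0, which was not checked. The model treats regions of an embryo as independent, so its p-values are too small, and 27 genes passed on section means and 502 with the number of genes detected as a covariate. With E20 sections 1 to 5 and 6 to 7 as separate blocks, chosen after seeing the data, 6 passed, and 0 when the 3 embryo slopes were tested (limma, 638 at an unadjusted p under 0.05).

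**Figure D3:**
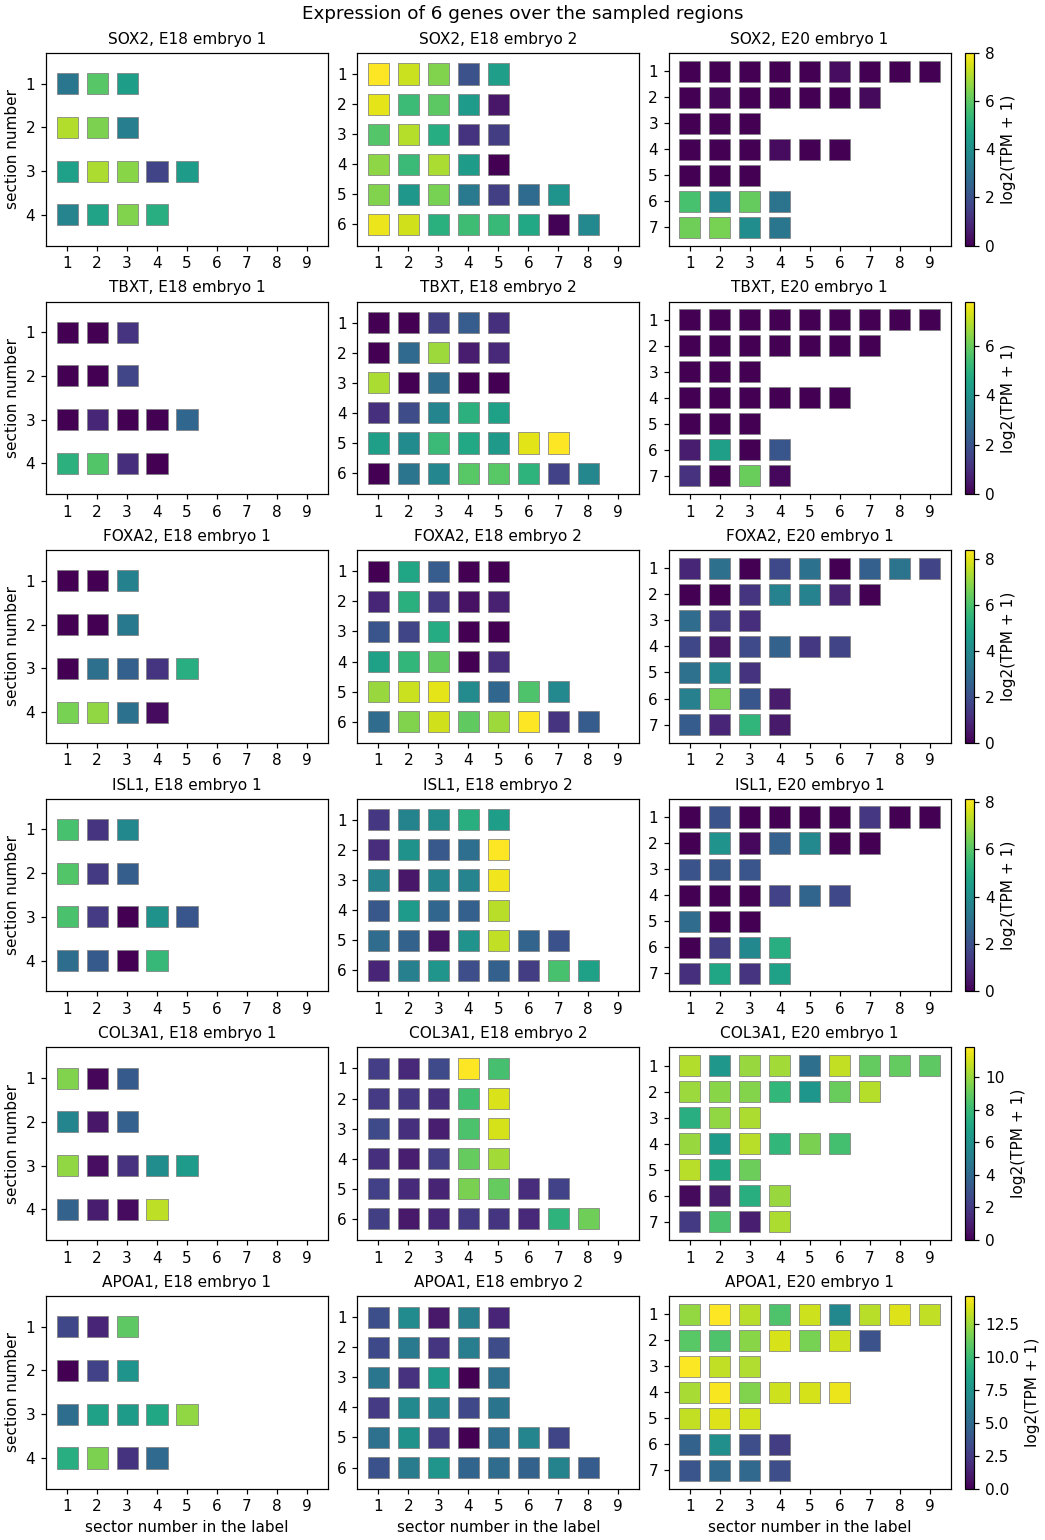
Expression of 6 genes, as log2(TPM + 1), over the sampled regions of each embryo, by section number (vertical) and sector number (horizontal); color gives the level, with 1 scale per gene. In E18 embryo 2, COL3A1 is high in sectors 4 and 5 of sections 1 to 5 and sectors 7 and 8 of section 6, and APOA1 is high in E20 sections 1 to 5 and low in sections 6 and 7.

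Across the sectors of a section, genes of blood and endothelium rose with sector number and genes of the epiblast fell. Without E18 embryo 2 no gene passed (limma, 1116 at an unadjusted p under 0.05). TGFBI, an extracellular matrix protein, rose by 3.27 ± 0.68 from the first to the last sector (SE, 86 regions; adjusted p = 0.00395), with slopes of 1.84, 6.00 and 1.46 in E18 embryo 1, E18 embryo 2 and the E20 embryo. The endothelial junction gene CLDN5 rose by 2.40 ± 0.50, with 1.34, 2.29 and 3.01, and the endothelial and blood progenitor gene CD34 by 2.28 ± 0.47. SOX2 fell by 2.38 on the log2 scale (SE 0.45; adjusted p = 0.00272), with slopes of -0.73, -5.19 and -0.60, and the WNT antagonist SFRP2 fell by 2.28, with -1.56, -3.39 and -1.62.

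The model with section as a block called 493 genes, 377 rising and 116 falling (405 and 319 after quantile normalization). Of the 493, 364 had the same sign in 3 of 3 embryos, beside 26.2% of all genes. This model too treats regions of an embryo as independent, so its p-values can be too small. The other large increases were those of the symbol MIR675 at 3.04 ± 0.81, SMCO3 at 2.75 ± 0.59, the hyaluronan link protein HAPLN1 at 2.73 ± 0.54 and ARHGDIB at 2.67 ± 0.57. They were followed by DEPTOR at 2.56 ± 0.49, urokinase (PLAU) at 2.44 ± 0.48 and RGS4 at 2.28 ± 0.51. MIR675 lies within the H19 transcript, and the values do not tell reads of that host apart. Other falling genes were the WNT receptor FZD5 at -2.20 ± 0.49, GDPD2 at -2.11 ± 0.49, GPC4 at -2.07 ± 0.47 and TMEM59L at -1.72 ± 0.36. SLC7A3 at -1.71 ± 0.45, the NODAL coreceptor TDGF1 at -1.71 ± 0.45, PTPRZ1 at -1.66 ± 0.47 and NFE2L3 at -1.60 ± 0.44 followed.

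Blood and endothelium genes rose in 9 of 14 cases (12 adjusted over the list alone), each with the same sign in 3 embryos, with TEK at 2.09, FLI1 at 1.79 and TIE1 at 1.61 (adjusted p = 0.0219 with an estimated correlation). Epiblast genes fell in 4 of 13 cases (9 adjusted over the list alone; adjusted p = 0.0334 with an estimated correlation). In the neural ectoderm list of 8, OTX2 fell by 2.29 and ZIC2 by 1.89 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0419 with an estimated correlation), but in E18 embryo 1 their slopes were 0.80 and 0.97. HOX genes rose in 10 of 31 cases (23 adjusted over the list alone), 7 of them with the same sign in 3 embryos, with HOXB5 at 1.94 and HOXA9 at 1.78. Extraembryonic mesenchyme genes rose in 8 of 15 cases (14 adjusted over the list alone), with COL3A1 at 3.63 and POSTN at 2.94, and 1 of them had the same sign in 3 embryos. Later mesoderm genes rose in 6 of 14 cases (9 adjusted over the list alone), with MEIS1 at 2.87 and SNAI2 at 1.91. These HOX, mesenchyme and later mesoderm lists each had adjusted p = 0.0720 with an estimated correlation. Amnion and surface ectoderm genes rose in 3 of 15 cases (10 adjusted over the list alone), with HEY1 at 2.68 and GABRP at 2.28 (adjusted p = 0.131 with an estimated correlation). Mesenchymal transition genes rose in 3 of 11 cases (8 adjusted over the list alone), with ZEB2 at 1.93 and VIM at 1.64 (adjusted p = 0.0838 with an estimated correlation). The yolk sac list (0 of 19 genes called by limma, 0 at an unadjusted p under 0.05) had a median of 0.16, a mean of 0.15 and a test pointing down. The ribosomal list (0 of 54 called by limma, 1 at an unadjusted p under 0.05) had a median of -0.0071, a mean of 0.0023 and a test pointing down. Neither list passed.

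**Figure D4:**
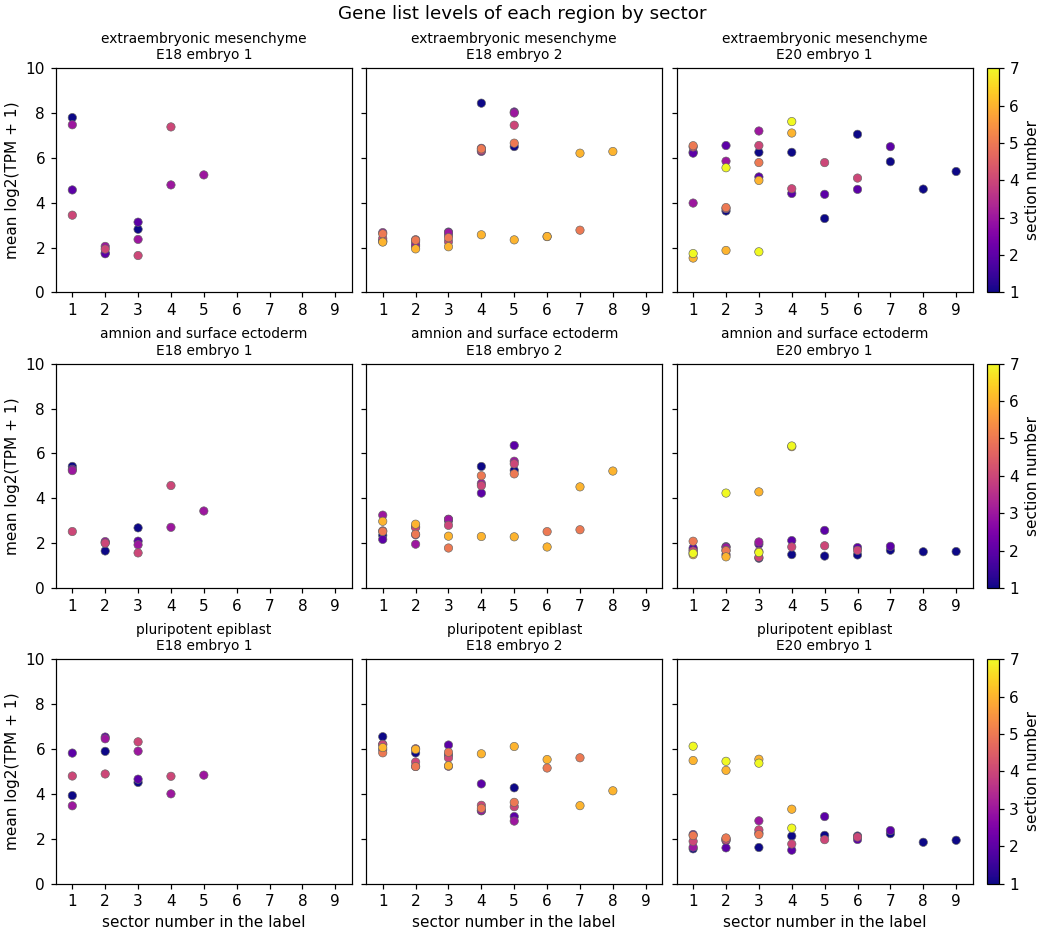
Level of 3 gene lists in each region, as mean log2(TPM + 1), by sector number, with 1 column per embryo and color for section number. In E18 embryo 2, 12 regions lie between 6.21 and 8.44 for the extraembryonic mesenchyme list and 23 between 1.94 and 2.78.

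E18 embryo 2 alone gave 1837 genes along the sectors, and each other embryo alone gave 0 (limma, 815 and 1288 at an unadjusted p under 0.05). In E18 embryo 2 the 12 regions high in the mesenchyme list were the last sectors of sections 1 to 4 and 6, and sectors 4 and 5 of section 5. The sector slopes of that embryo were not separated from this split. In E18 embryo 1 the list was highest in sector 1 of sections 1 to 3 (7.79, 4.57 and 7.47) and in sector 4 of section 4 (7.38). Slopes differed between embryos for 73 genes, 253 genes passed with a pseudocount of 0.1, 1129 without E18 embryo 1, 325 with sector numbers as given, and 0 when the 3 embryo slopes were tested (limma, 882 at an unadjusted p under 0.05).

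Because the labels name no tissue, genes were also related to the level of 7 marker lists within embryos. Each value is a slope per SD of the list's score (86 regions, embryo as a block, list members tested against the score without them). Regions of an embryo are treated as independent here too, so the SE and p-values can be too small. Slopes of a list's own members show that the chosen markers vary together and are no independent result. The genes following the epiblast score most steeply included transcription factors of epiblast and anterior ectoderm. OTX2 rose by 2.03 ± 0.17 per SD (SE; adjusted p = 3.05e-18), ZIC2 by 1.94 ± 0.12 and the retinoic acid hydroxylase CYP26A1 by 1.86 ± 0.18. SOX2 rose by 1.80 ± 0.12, L1TD1 by 1.76 ± 0.12 and ANOS1 by 1.70 ± 0.09. SFRP2, SLC7A3, PTPRZ1 and DPPA5 completed the 10 largest increases, down to 1.67. The collagen COL3A1 fell by 2.70 per SD, LUM by 2.55, POSTN by 2.23, IGFBP3 by 2.05, TGFBI by 2.03 and PMP22 by 1.93. FGB, RBP4 and SPINK1 fell by 2.16, 2.00 and 1.94, but FGB had slopes of -0.39 and -0.061 in the E18 embryos and -4.91 in the E20 embryo. The score had 6194 genes called, 4143 rising and 2051 falling, 4862 of them with the same sign in 3 embryos. Of the list's own 13 genes 12 rose (12 adjusted over the list alone), SOX2, L1TD1 and SFRP2 among them, and LIN28B did not pass.

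Genes following the primitive streak score and the definitive endoderm and node score overlapped. FGF17 rose by 2.59 ± 0.18 per SD of the streak score (adjusted p = 3.16e-22) and by 2.48 ± 0.19 per SD of the node score (adjusted p = 2.69e-18). DKK4 rose by 2.43 and 2.21, LHX1 by 2.27 and 2.14, CER1 by 2.23 and 2.16, MIXL1 by 2.40 and 1.68, and the cartilage-type collagen COL9A2 by 1.74 and 1.67. EOMES at 2.01, KHDC3L at 1.77 and SP5 at 1.68 also followed the streak score. FOXA2 at 1.89, DKK1 at 1.66, CHRD at 1.62 and the axonemal gene DNAJB13 at 1.57 also followed the node score. LUM, COL3A1, IGFBP3, POSTN, AQP1, DCN and TEK fell with both scores, with slopes of -1.14 or lower. The streak score had 3300 genes called (2701 rising, 599 falling, 2451 with the same sign in 3 embryos) and the node score 2345 (1906, 439 and 2104). After quantile normalization the counts rising and falling were 1246 and 1052 for the streak score and 717 and 669 for the node score. Of genes rising with the same sign in 3 embryos, 1183 followed both scores, an overlap without a test because the scores share regions and are themselves related. All 16 streak genes rose with their score and 11 of 12 node genes with theirs (16 and 12 adjusted over the list alone), FOXA3 being the exception over all genes. Of the rising genes named here, FGF17, MIXL1, LHX1, EOMES and SP5 belong to the streak list, and FOXA2, CER1 and CHRD to the node list.

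Genes following the hypoblast and yolk sac endoderm score with the largest slopes were plasma protein genes and the trypsin inhibitor SPINK1. FGB rose by 3.03 ± 0.27 per SD (adjusted p = 1.73e-15), with slopes of 2.05 in E18 embryo 1, 0.74 in E18 embryo 2 and 5.66 in the E20 embryo. SPINK1 rose by 2.72 ± 0.22, transthyretin (TTR) by 2.65 ± 0.20, with 2.93, 0.91 and 4.23, APOA2 by 2.62 ± 0.23 and APOA1 by 2.37 ± 0.25. FGG, RBP4, AFP, FGA and AHSG rose by 2.12 to 2.58. VTCN1 fell by 1.30, SLC7A3 by 1.08, SOX2 by 1.06 and L1TD1 by 1.03, followed by PTPRZ1, SLC7A5, TMEM54, TDGF1, ANOS1 and CPZ. The score had 2145 genes called, 909 rising and 1236 falling, 1492 with the same sign in 3 embryos. Of the 19 list genes 17 rose (17 adjusted over the list alone), and GATA4 and GATA6 did not pass.

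The amnion, later mesoderm and extraembryonic mesenchyme scores shared many of their genes. With the amnion and surface ectoderm score, the sphingosine phosphate transporter SPNS2 rose by 2.14 ± 0.13 per SD (adjusted p = 3.56e-25), the GABA receptor subunit GABRP by 1.98 ± 0.12 and INSL4 by 1.95 ± 0.13. The uroplakin UPK2 rose by 1.88 ± 0.11 and CT55 by 1.87 ± 0.14, and these 5 genes had slopes of at least 1.32 in each of the 3 embryos. COL3A1 at 2.27, HAND2 at 1.96, PMP22 at 1.91, COL1A2 at 1.82 and POSTN at 1.81 rose too, with POSTN slopes of 2.89, 2.97 and 0.24. With the later mesoderm score, HAND1 rose by 1.92 ± 0.15 (adjusted p = 4.06e-19), HAND2 by 1.88 ± 0.18 and HAPLN1 by 1.73 ± 0.13, beside COL3A1, PMP22, POSTN, COL1A2, TGFBI, MIR675 and LUM at 1.79 to 2.39. The mesenchyme score was followed by COL3A1 at 3.25 ± 0.12 (adjusted p = 9.97e-41), POSTN at 2.79 ± 0.12, LUM at 2.60 ± 0.18 (SE) and COL1A2 at 2.56 ± 0.08. It was also followed by IGFBP3 at 2.50 ± 0.11, DCN at 2.36 ± 0.13, PMP22, TGFBI, MIR675 and HAND2. Members of their score's own list were GABRP (amnion), HAND1 (later mesoderm) and COL3A1, POSTN, LUM, COL1A2, DCN and HAND2 (mesenchyme).

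Other genes fell as these 3 scores rose. APOA1 fell by 1.28 per SD of the amnion score, AHSG by 1.18, FOXA2 by 1.11 and CKB by 1.10, followed by MGST1, METTL7B, APOB, CA4, MT1M and SAMD3. OTX2 fell by 1.24 per SD of the later mesoderm score, SFRP1 by 1.23, SFRP2 by 1.15 and USP44 by 1.13, followed by ITGA7, GDF3, GDPD2, HESX1, SOX2 and ZIC2. OTX2 fell by 1.84 per SD of the mesenchyme score, FGF17 by 1.61, ZIC2 by 1.59, LHX1 by 1.59, CYP26A1 by 1.57 and SFRP1 by 1.48, followed by EOMES, FOXA2 and CER1. Genes called were 3032 for amnion (2108 rising, 924 falling, 2418 with the same sign in 3 embryos), 3036 for later mesoderm (2254, 782 and 2805) and 4687 for mesenchyme (2282, 2405 and 4242). After quantile normalization 1868 rose and 1836 fell with the amnion score, and 1866 rose and 2082 fell with the later mesoderm score. All 15 amnion and 15 mesenchyme genes rose with their score, and 12 of 14 later mesoderm genes did, without TCF15 and FOXC1 (the same counts adjusted over the list alone). Rising genes with the same sign in 3 embryos that later mesoderm and mesenchyme shared numbered 1524, again without a test for the same reason.

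Testing the 3 embryo slopes, the counts over the 7 scores, in the order described, were 129, 37, 736, 0, 94, 854 and 1415 (limma; for the yolk sac score 905 at an unadjusted p under 0.05). The yolk sac score had 11 genes called without the E20 embryo and 387 with separate E20 blocks, where 304 of its calls were shared in direction and 226 took the opposite sign.

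Relations between the scores themselves were tested across regions within embryos, as 84 pairs in 4 strata, leaving out pairs in which a score split into clusters (a gap over 0.3 of its range). The E20 strata and this rule were chosen after seeing the data. In E18 embryo 1 (15 regions) 2 of 6 pairs passed, and in E18 embryo 2 (35 regions) 6 of 15. Epiblast and later mesoderm scores ran opposite in embryo 1, with Pearson's r = -0.819 (permutation p = 0.00028, adjusted 0.0018; Spearman's rho -0.796, p = 0.00069, adjusted 0.00362; r = -0.772 without the 2 farthest regions). Streak and node scores ran together in embryo 2, with r = 0.575 (permutation p = 0.00025, adjusted 0.00175; rho 0.659, p = 1e-05, the smallest these permutations can give, adjusted 0.00012; r = 0.641 without 2 regions). The other 5 pairs that passed there involve the epiblast or the amnion list. These 2 lists follow the split of the mesenchyme list in embryo 2. Its 12 high regions had epiblast levels of 2.79 to 4.45 against 5.15 to 6.55 elsewhere, and amnion levels of 4.23 to 6.36 against 1.78 to 3.25. The 5 pairs may therefore restate that split, and no correlation was computed within either set of regions.

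In sections 1 to 5 of the E20 embryo (28 regions) 6 of 10 pairs passed. Yolk sac and mesenchyme scores ran opposite, with r = -0.602 (permutation p = 0.0003, adjusted 0.0018; rho -0.749, p = 1e-05, adjusted 0.00012; r = -0.624 without the 2 farthest regions). Later mesoderm and mesenchyme scores ran together, with r = 0.747 (permutation p = 1e-05, adjusted 0.00012; rho 0.692, p = 7e-05, adjusted 0.000535; r = 0.665 without 2 regions). Epiblast and later mesoderm had r = 0.487 there (permutation p = 0.00865, adjusted 0.0304; rho 0.523, p = 0.0047, adjusted 0.0180; r = 0.319 without 2 regions), and its difference from E18 embryo 1 was not tested. The epiblast list lay at 1.49 to 2.99 in these E20 sections and at 3.47 to 6.53 in E18 embryo 1, as mean log2(TPM + 1). Its score in these E20 sections therefore ranks low values of the list, and the 2 correlations do not compare like levels. Regions of 1 embryo are not independent animals, and in E20 sections 6 and 7 (8 regions) no pair was free of clusters.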

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

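The tests of the 3 patterns weighed here, and the counts with another embryo alone in place of the E20 embryo, were chosen only after the results were seen, while the shuffles of sections, sectors and scores were set up before.

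The slope along sections differed between embryos for 1537 genes and the slope along sectors for 73 (moderated F test of the difference). Among the panel genes, the section slopes of NANOG differed (adjusted p = 0.00634; 0.043, 0.015 and 3.50 in E18 embryo 1, E18 embryo 2 and the E20 embryo). Those of SOX2 (adjusted p = 0.00654; 0.13, -0.56 and 4.55), TFAP2A (adjusted p = 0.0214; -1.18, -1.16 and 2.85), APOA1 (adjusted p = 0.00189; 3.19, 1.21 and -6.74) and TTR (adjusted p = 3.73e-05; 1.23, 1.40 and -8.59) did as well. Sector slopes differed for SOX2 (adjusted p = 0.00230; -0.73, -5.19 and -0.60) and OTX2 (adjusted p = 0.0311; 0.80, -5.08 and -1.23).

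Within sections of 4 to 10 regions, 10 of 130 groups of values had a region standing apart from the others by Dixon's test, which chance alone gives in about 5% of groups. Genes at a TPM of at least 1 numbered 13958 in E18 embryo 2, section 5, sector 3 (others 11934 to 12661) and 13702 in section 6, sector 4 (others 11418 to 12132). The summed TPM was 495547.3 in E18 embryo 1, section 3, sector 3 (others 616649.8 to 657043.5). The mitochondrial share was 26.04% in E20 section 1, sector 4 (others 14.5% to 19.3%). The yolk sac list averaged 5.09 in E18 embryo 1, section 3, sector 5 (others 0.94 to 1.89), 2.85 in E18 embryo 2, section 6, sector 7 (others 1.10 to 1.76) and 1.74 in E20 section 2, sector 7 (others 5.74 to 8.78), as mean log2(TPM + 1). On the same scale the epiblast list averaged 6.32 in E18 embryo 1, section 4, sector 3 (others 4.78 to 4.89), the definitive endoderm and node list 1.21 in E20 section 4, sector 3 (others 1.74 to 1.92) and the later mesoderm list 4.94 in E18 embryo 2, section 5, sector 5 (others 1.86 to 2.98).

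The hypoblast and yolk sac endoderm list was higher at E20 than at E18, with a median of 5.34. The share of mitochondrially encoded RNA does not account for it. That share was at most 48.8% of the summed TPM in any region, too little for a difference of this size. The median of 5.43 without those genes was therefore foreseeable and adds no separate evidence. A stage difference shared by all parts of the E20 embryo is argued against by section 7, where the highest region had a list median difference of -0.80. Section medians were -0.93 in section 6 and -0.98 in section 7, beside values above 5 in sections 1 to 5. Different tissue in different E20 sections could give such values, as a hypothesis made from the same data. With 1 E20 embryo, a stage difference within either tissue stays open.

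Over all genes, E18 embryo 2 had higher values than E18 embryo 1, with a median of 0.41. Its larger mitochondrial share works the other way, since a larger share lowers the TPM of all other genes. The median over the same genes was 0.70 without the mitochondrially encoded genes, a direction the shares largely set in advance. The difference was larger in the middle class of 3 by mean TPM than in the upper class by 0.39, with medians of 0.59, 0.47 and 0.075 from the lower to the upper class. With 1 embryo against 1, and with more genes detected in embryo 2 showing in the same values, this does not decide whether fewer genes detected in E18 embryo 1 explain the difference. That explanation and a biological difference between the embryos, which was not tested, stay open.

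Of the 28 streak and node genes, 17 rose along the sections. With E20 sections 1 to 5 and 6 to 7 as separate blocks 5 of the 17 still passed, and the same 5 without the E20 embryo (FGF17, FOXA2, HHEX, GSC and CHRD). The 12 calls that ended had a median slope of 2.33 (median SE 0.505) in the reported model, 1.72 (0.59) with separate blocks and 2.11 (0.75) without the E20 embryo. Slopes were smaller in 11 of the 12 with separate blocks and in 4 without the E20 embryo, and all 12 errors were larger in both settings. Since the 12 were picked by the loss of their calls, these changes do not measure the share of the step. All 17 genes kept rising in both settings. Their median slope was 2.465 as reported, 2.375 with separate blocks and 3.03 without the E20 embryo. The step between E20 sections 5 and 6 cannot enter the slopes of the E18 embryos, where 23 (embryo 1) and 28 (embryo 2) of the 28 genes rose. In E18 embryo 2 the median slope of 1.87 was exceeded or equalled by 17 of 720 orders of its sections (exact one-sided p = 0.0236, the smaller of 2, with a highest other value of 2.20). In E18 embryo 1 the slope was 2.01 (exact one-sided p = 0.0833 over 24 orders, which cannot give a p under 0.05 unless the real order ranks first). The direction came from the same data and the p-values are not adjusted for 2 embryos. These orders therefore do not decide whether the E18 embryos hold a trend of their own. The number of genes detected does not account for the calls, since 15 of the 17 passed with that number as a covariate. A biological, position-dependent signal of these genes stays possible, a hypothesis found and tested on the same data.

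The 3 choices of a lone embryo are too few for a share under 0.05, with only the real choice giving 1734 genes (1 of 3, itself included) and a highest other count of 1303. The shares below also count the real order. For the section trend 1 of 100 orders, the real one, gave 1628 genes or more, which excludes chance order at this level, but the highest other order gave 1444, which is close to the real count. For the sector trend 1 of 100, the real one, gave 493 or more, with a highest other of 8. For the scores, only the real one of 100 (1 of 100) gave as many genes in each case, with real and highest other counts of 6194 and 2 (epiblast), 3300 and 26 (streak), 2345 and 97 (node), 2145 and 92 (yolk sac), 3032 and 97 (amnion), 3036 and 6 (later mesoderm) and 4687 and 3 (mesenchyme). The shuffles move single regions and ignore sections and tissue blocks, so they exclude only an order of single regions by chance. The yolk sac score, with 0 genes on embryo slopes and 11 without the E20 embryo, is not secured by them.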

How the results depend on the processing

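The alternatives without mitochondrially encoded genes, with single E20 sections or with E20 sections 1 to 5 and 6 to 7 as blocks, and all those for the E18 difference and the comparisons of slopes, were chosen only after the results were seen. Of 146 alternative values of the main counts and shares, 92 stayed within 1.5 times of the reported value and 54 were counted as moved. The variance shares were counted as moved without this rule, although they lay within 1.5 times. Of 3165 values of named genes 311 no longer passed, 46 newly passed, 41 reversed and 2767 were counted as unchanged. Reversed values changed sign, and the opposite direction need not have passed. The unchanged include values that changed sign without passing in either fit. They also include stage values with an embryo left out, which have no p-value. Leaving out regions with under 0.6 of their embryo's median genes removes 0 regions and gave no value. No paired analysis was possible because no label pairs samples across stages or embryos. Depth is unknown, so what it limits cannot be computed.

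The stage count was 887 without mitochondrially encoded genes, 0 with medians over regions, 2711 with an estimated correlation within embryos (0.12), and 3451, 3351, 3077, 3068, 3021, 30 and 17 with E20 sections 1 to 7 alone. With section 6 alone the named differences reversed for FGB (-1.47), AFP (-0.066), FGG (-0.73), AHSG (-0.22), RBP4 (-1.14), TF (-0.47), APOA2 (-0.90), FGA (-0.66), SERPINA1 (-0.98), APOA1 (-1.03), TTR (-2.08), OTX2 (0.23), TMEM54 (0.35), CNFN (0.86), MIXL1 (1.62), EOMES (0.53), NANOG (0.073) and CER1 (0.46). With section 7 alone they reversed for FGB (-1.57), AFP (-0.69), FGG (-0.83), AHSG (-0.25), RBP4 (-1.43), TF (-0.31) and APOA2 (-1.32). FGA (-0.66), SERPINA1 (-0.98), APOA1 (-1.21), TTR (-2.07), CNFN (0.19) and ZIC2 (0.11) reversed as well. So did MIXL1 (1.49), EOMES (0.71), NANOG (0.0235), SOX2 (0.085) and CER1 (0.068). Reversed means here only a change of sign, and several of these values lay near 0. With 1 section on the E20 side, they do not show differences in the opposite direction.

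The section count was 0 for embryo slopes, 27 on section means, 502 with genes detected as a covariate and 6 with separate E20 blocks, where SERPINA1 (0.33), PLG (0.33), APOM (0.25) and TTR (1.30) reversed. The TTR slope lay between -5.55 and 1.35 with each embryo left out, reversed without the E20 embryo. The sector count was 253 with a pseudocount of 0.1, 0 for embryo slopes and 325 with sector numbers as given. Sector slopes differed between embryos for 22 genes with a pseudocount of 0.1, 37 with the stricter filter and 164 after quantile normalization. Genes at least 1 apart between the E18 embryos were 6073, 1231, 998 and 4945 with a pseudocount of 0.1, the stricter filter, quantile normalization and no mitochondrially encoded genes. For the scores of epiblast, streak, node, yolk sac, amnion, later mesoderm and mesenchyme, embryo slopes gave 129, 37, 736, 0, 94, 854 and 1415. Separate E20 blocks gave 3800 (epiblast), 1171 (streak) and 387 (yolk sac), the covariate 1415 (yolk sac), quantile normalization 1386 (node) and removal of mitochondrially encoded genes 1399 (node). With each embryo left out in turn the ranges were 9 to 2411 (section), 0 to 1129 (sector), 1368 to 3379 (streak), 608 to 2263 (node), 11 to 3437 (yolk sac), 1522 to 4380 (amnion), 1143 to 3487 (later mesoderm) and 2109 to 4979 (mesenchyme). The lowest was without the E20 embryo for section, streak and yolk sac, and without E18 embryo 2 for the others. Lists passing fell to 2, 0 and 3 with an estimated correlation, and with a pseudocount of 0.1 the variance shares were 20.2%, 15.2% and 63.2%. Fewer embryos, slopes or genes tested are part of these settings, and otherwise the cause was not tested.

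Median shifts of all genes (stage, section, sector) were -0.44, 0.11 and 0.075 as reported, -0.95, 0.28 and 0.15 with a pseudocount of 0.1, -0.0088, -0.023 and -0.015 after quantile normalization, and -0.67, 0.14 and 0.095 without mitochondrially encoded genes. Counts up and down after quantile normalization were 796 and 679 (stage), 852 and 500 (section), 405 and 319 (sector), 3441 and 2867 (epiblast), 1246 and 1052 (streak), 717 and 669 (node), 1868 and 1836 (amnion) and 1866 and 2082 (later mesoderm). Without mitochondrially encoded genes they were 902 and 497 (node), 785 and 1808 (yolk sac) and 1754 and 1021 (later mesoderm).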

Other observations

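The grouping of regions was noticed only after the results were seen. In E18 embryo 2 the extraembryonic mesenchyme list split the regions, with 23 of 35 between 1.94 and 2.78 and 12 between 6.21 and 8.44 on the log2 scale, and a gap of 3.43 that made up 0.529 of the range. The 12 regions were sectors 4 and 5 of sections 1 to 5 and sectors 7 and 8 of section 6. No test was made between these regions, since they were found by the list itself.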
